A study of Mus musculus with 8 samples.

How the data were processed

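RNA of 4 control and 4 Irf2_AhcKO samples of sorted Lgr5-high intestinal stem cells was measured on 8 Agilent 1-colour arrays. The series design speaks both of 4 independent mice per genotype and of 2 biological replicates. What the replicates refer to is unclear, so the p values measure the spread between these samples. Groups were taken from the labels, although the names of the scanner data of control replicates 3 and 4 mention Ah-Cre as well. Per the labels' protocols, total RNA was extracted with RNeasy columns, amplified with an Ovation Pico WTA kit and labelled with Cy3. Such amplification starts from little RNA and can distort the levels of individual transcripts. The deposited scanner files hold 62976 spots per array, 59305 of them not controls. Per the file headers and the submitters' processing notes, they were made with Agilent Feature Extraction 11.5.1.1, which gives for each spot a background-subtracted and detrended intensity. The authors' deposited series table holds the same intensity multiplied by 1 constant per array, between 6.41 and 6.90, on a linear scale and without centring. How that constant was chosen is not given in the sources used here. The medians of the table's columns lay between 207 and 246.

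The 55681 probes were named through the accession in the files and a RefSeq gene table of assembly GRCm38.p6, and since the array's grid was annotated on mm9 no coordinates are printed. A symbol was found for 28331 probes (21368 symbols), no probe had several genes, and 27350 stayed unnamed. Unnamed features were tested under their own identifiers.

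The processed intensity was put on a log2 scale and each array's 75th percentile over spots that were not controls was subtracted. Spots of a probe were averaged without outlier spots, of which there were between 141 and 214 per array, unless all of a probe's spots were outliers. Probes were kept when well above background on at least 4 of the 8 arrays, and each gene was represented by its kept probe of highest mean. This left 25404 features, 15114 of them with a symbol. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the slide as a term and Benjamini-Hochberg adjusted p below 0.05 as the threshold. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Of 499 list entries, 386 different genes were measured.

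Slides and scans coincided, with slide 1 holding replicates 1 and 2 of both groups and slide 2 replicates 3 and 4. The slide carried 47.7% of the variance as first principal component, and 9016 features (35.5%) differed between slides. Same-numbered arrays deviated together from their group means (r across genes 0.46, 0.49, 0.52 and 0.53), which by the rule fixed for this comparison makes the numbers pairs. With the slide means removed as well, r was 0.05 for replicates 1 and 2 and 0.21 for replicates 3 and 4, so most of the pairing came through the slide that the model already holds. The labels describe separate mice and do not say that a number marks a shared litter or day. Arrays of 1 group on 1 slide correlated at 0.986 to 0.988, and no pair of arrays held identical values. Replicate 4 of each group had Xist signal (5.83 and 5.88) and low Ddx3y (-6.35 and -6.46), unlike the other 6 arrays, so the sexes were balanced between groups.

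The model, the lists and the rule for named genes were written before the data were examined. The rule names Irf2, the 12 most increased and 12 most decreased passing genes with the same sign on both slides, and up to 4 members of each list by unadjusted p. How many members a list gives within that limit (4 where the list or a member passed, otherwise 2) was set after the list tests were seen. Rtp4, Oas1a, Sis, Lgr5 and the genes of families in the closing section were chosen after their values were seen. The single values of some list members that the rule takes are not reported here, while the list tests and counts include them.

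On 10 simulated data sets of 25404 features with the real means, limma's moderated variances and 200 changed genes, the comparison of Irf2_AhcKO against control recovered 73.5% of 2-fold and 94.6% of 4-fold changes. Among calls, 5.88% were false. With the replicate block the shares were 60.2% and 91%. In 10 further sets with no changed gene, 1 feature and 1 list passed in all. Simulated genes were independent, so this says nothing about correlated lists. Simulated arrays had no tie between same-numbered pairs either, so the shares may differ in the real data. The moderated variances differ less between genes than unmoderated ones, and 200 changed genes ease the adjusted threshold. The shares are therefore no estimate of how many real changes were recovered. In the real data Msrb2 passed at a log2 difference of -2.98. Apol7a at 2.90 and Ifit2 at 2.55 did not (limma adjusted p = 0.0658 and 0.0516).

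Alternatives were normexp background correction with an offset of 50, quantile normalization, no filter and a stricter filter on dim probes, no slide term, the slide as a random block, each slide alone, the replicate block, the mean of a gene's probes, trended and robust eBayes, the series table, a 2-fold limit and leaving out each array. The mean spot signal planned for normexp is not among the columns used here, and the median spot signal with the local background median took its place. For the random block and the trended fit, lists were tested with the preranked form of camera. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.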

Results

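Intestinal stem cells sorted for high Lgr5 reporter signal were profiled on 1-colour expression arrays from mice with a floxed Irf2 gene. IRF2 is a transcription factor that binds interferon response elements. Per the labels, the control samples had the floxed gene and the Lgr5 reporter allele, and the samples labelled Irf2_AhcKO an Ah-Cre transgene in addition, with 4 samples in each group. The names given to the scanner data of control replicates 3 and 4, both on slide 2, mention Ah-Cre as well, so whether those controls carried the recombinase is not settled. Ah-Cre is a recombinase driven by a xenobiotic-inducible promoter, which β-naphthoflavone switches on. Cells were taken 1 month after 5 consecutive days of β-naphthoflavone, and each array held the RNA of 1 sample. The arrays lay on 2 slides, each with 2 control and 2 Irf2_AhcKO arrays. Between 61.4% and 69.8% of the spots were well above background, and no spot was saturated on any array. Array data carry no read depth, so the number of arrays limits the precision. The design asks what loss of Irf2 does to gene expression in these stem cells.

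Irf2 itself was measured by 1 probe and was not lower in the arrays labelled Irf2_AhcKO. Its log2 signal relative to the array's 75th percentile was 0.64 ± 0.26 (SD, n = 4) in controls and 0.91 ± 0.23 (SD, n = 4) in Irf2_AhcKO. The log2 difference was 0.27 (SE 0.12, limma adjusted p = 0.429), with 0.34 on slide 1 and 0.21 on slide 2. The position of this probe relative to the deleted part of the gene is not given in the sources used here, so the probe may check nothing about the deletion. The signal goes against the label as it stands, and every direction below is therefore between the arrays labelled Irf2_AhcKO and the arrays labelled control.

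Between the labelled groups, 25 of 25404 features passed the threshold, 14 higher and 11 lower in Irf2_AhcKO, and 23 of them carried a gene symbol. Among the higher genes were Ifit1, an interferon-induced protein that binds viral RNA, and Ifit1bl1, its near-copy, with a log2 difference of 2.55 (SE 0.26, limma adjusted p = 0.0329). Ifit1 was not well above background on any control array and was at least 2.41-fold higher in Irf2_AhcKO (limma adjusted p = 0.0107). The floor of such a bound is, on each control array, the higher of the gene's own signal and the lowest signal among probes well above background. A higher floor would give a smaller bound. Here and below, "at least" is therefore meant against this floor and is no strict minimum. C4bp, a regulator of complement, was likewise at least 3.22-fold higher (adjusted p = 0.048). These bounds hold for the processed signal only, since with normexp Ifit1 had a log2 difference of 0.46 and C4bp one of 0.42. Tapbp, the tapasin that loads peptides onto MHC class I, rose by a log2 difference of 1.03 (SE 0.12, adjusted p = 0.0482). The purine enzymes Xdh, Pnp2 and Pnp were higher by log2 differences of 1.98, 1.64 and 0.95, and the probes of the near-copies Pnp and Pnp2 may read each other.

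The other higher genes were Clic5 (log2 difference 2.02), Asb13 (1.62), Sectm1a (1.51), Tasor2 (1.02) and Taf7 (0.97). Among the lower genes, Msrb2, a methionine sulfoxide reductase, fell by 2.98 on the log2 scale (SE 0.22, limma adjusted p = 0.0115). Cadps2, a factor of dense-core vesicle release, fell by 2.65 (SE 0.16, adjusted p = 0.0107), and all 3 of its probes were lower. Gsdmd, the pore-forming protein of pyroptosis, fell by 1.15 (SE 0.12, adjusted p = 0.0329). Nmi, a partner of STAT proteins, fell by 1.09 and the interferon-inducible Ifi27l2b by 1.08. The metabolic genes Aldh1a1 (retinaldehyde oxidation), Akr1c14, Khk (fructose phosphorylation) and Asah2 (ceramide breakdown) had log2 differences of -1.79, -1.59, -0.999 and -0.95. Zfp516 had a log2 difference of -2.29, with 1 of 4 Irf2_AhcKO arrays well above background, and Lgi3 one of -1.56, with 2 of 4. With normexp, whose offset draws dim signals together, 10 of the 23 values with a symbol shrank by more than 1.5 times. Besides Ifit1 and C4bp these were Ifit1bl1 (1.69), Sectm1a (0.75), Taf7 (0.55), Msrb2 (-1.78), Akr1c14 (-0.86), Asah2 (-0.38), Zfp516 (-0.73) and Lgi3 (-0.31), and of the 10 only Lgi3 then missed the threshold.

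All 25 features had the same sign on both slides and groups that did not overlap. Both follow largely from the selection, since the threshold was applied to these same arrays. Over all features tested, the groups did not overlap in 977 (3.85%), where chance would give 2.86% if all arrays were interchangeable. They were not, since 35.5% of the features differed between slides, so that share is no exact reference for this design. Without the Benjamini-Hochberg adjustment, 2980 features had p below 0.05, where chance over independent features gives 1270 and another split of the same arrays gave 3536. That split kept the labelled contrast on slide 1 and set replicates 3 against replicates 4 on slide 2. It is therefore no pure measure of chance. The count of 25 was not stable: with the replicate number as a block no feature passed (3293 had an unadjusted limma p below 0.05), and within either slide alone none passed (2539 and 1337). Leaving out 1 array gave between 0 and 25 calls.

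**Figure D1:**
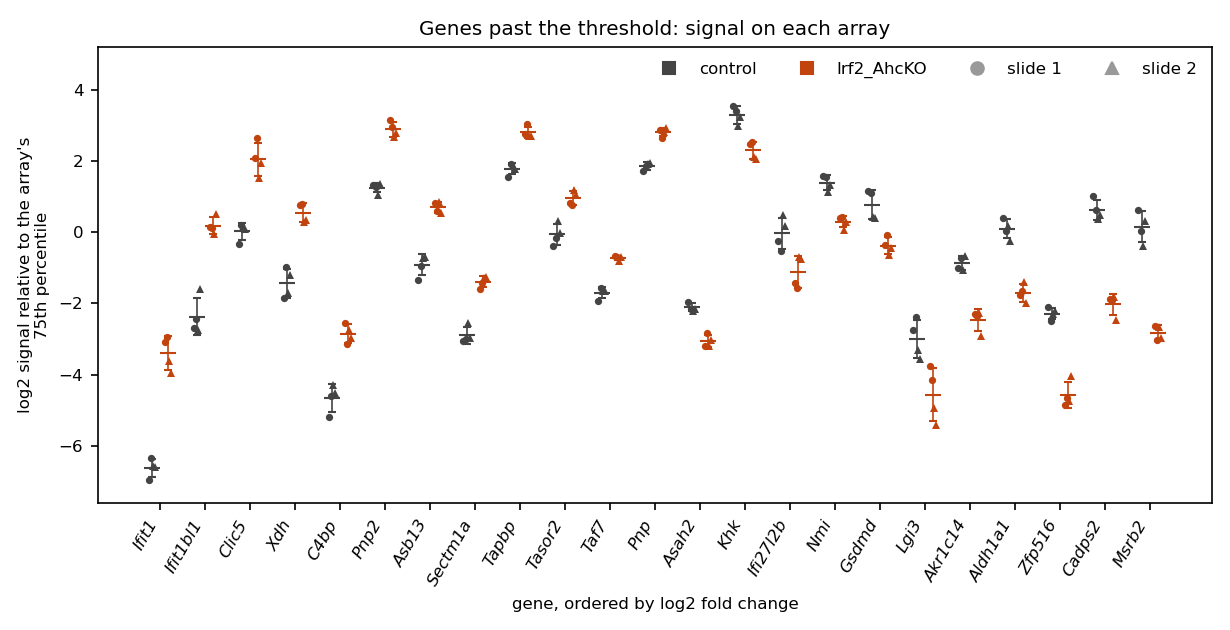
Log2 signal relative to each array's 75th percentile (y axis) for the 23 genes with a symbol past the threshold, ordered by log2 fold change (x axis), in 4 control and 4 Irf2_AhcKO arrays. Points are arrays, circles on slide 1 and triangles on slide 2, and bars are the mean and SD. The 2 groups do not overlap in any of the 23 genes, which were chosen on these same arrays. Ifit1 and C4bp were not well above background on any control array, and Zfp516 and Lgi3 not on 3 and 2 of the 4 Irf2_AhcKO arrays.

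With camera's preset correlation, lists tied to interferon gamma and to MHC class I and II were higher in the arrays labelled Irf2_AhcKO. Among their members, part of the interferon gamma-inducible genes, part of the MHC class I and antigen processing genes, and the MHC class II genes rose. Fry in 1 direction called none of these lists, with adjusted p of 0.1125, 0.1092 and 0.1878 in that order. Adjustment over a list alone does not span the 31 lists. Of 18 measured interferon gamma-inducible GTPases and chemokines, 7 rose and none fell with p adjusted over the list alone, and 17 of 18 had a positive difference, while none passed over all genes. Cd274, the T-cell inhibitory ligand PD-L1, was not well above background on any control array and was at least 3.86-fold higher. This bound holds for the processed signal only, and with normexp the difference was smaller than the bound. Among the GTPases of defence against intracellular pathogens, Gbp6 rose by a log2 difference of 1.73 (SE 0.34), Gbp10 by 1.39 (SE 0.25) and Irgm1 by 0.83 (SE 0.14). The list's median log2 difference was 0.49, at 1.00 on slide 1 and 0.47 on slide 2 (camera adjusted p = 9.93e-08, and adjusted p = 0.442 with an estimated correlation). The median was 0.24 with normexp and 0.38 without Irf2_AhcKO replicate 2, whose list mean of -0.44 lay above those of the other Irf2_AhcKO arrays (-1.58 to -1.25). Markers of T and intraepithelial lymphocytes had a median of 0.15 (camera adjusted p = 0.203).

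All 7 measured MHC class II genes rose with p adjusted over the list alone, and none passed over all genes. H2-Aa rose by a log2 difference of 1.42 (SE 0.37), H2-Ab1 by 1.18 (SE 0.33), H2-DMa by 1.00 (SE 0.26) and H2-Eb1 by 0.83 (SE 0.27). MHC class II molecules present peptides to CD4 T cells. The groups overlapped in H2-Aa, H2-Ab1, H2-DMa and H2-Eb1. The estimated correlation between the list's genes was 0.91, so the 7 genes do not count as separate observations. The list's median was 1.03, at 1.59 on slide 1 and 0.62 on slide 2 (camera adjusted p = 1.19e-05, and adjusted p = 0.632 with an estimated correlation). Over 20 leukocyte markers well above background on all 8 arrays, the mean log2 shift was 0.12, with a 95% interval from 0.02 to 0.22. Of the 17 MHC class I and antigen processing genes, 7 rose and none fell over the list alone, 10 did not pass, 4 of the 17 had a negative difference, and Tapbp passed over all genes. Psmb8, a subunit of the immunoproteasome, rose by 1.76 (SE 0.34), Tapbpl by 0.75 (SE 0.17) and H2-T10 by 0.46 (SE 0.10), with a list median of 0.27 (0.39 on slide 1, 0.25 on slide 2). The camera adjusted p was 1.65e-05, and adjusted p = 0.442 with an estimated correlation.

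The genes usually grouped as type I interferon targets moved both ways. Of 29 measured members, 8 rose and 10 fell over the list alone, and Ifit1 passed over all genes. Ifit2 rose by a log2 difference of 2.55 (SE 0.30) and Dtx3l by 0.82 (SE 0.13). Dhx58, a regulator of RNA sensing, was at least 1.90-fold lower, with no Irf2_AhcKO array well above background. This bound holds for the processed signal only, and with normexp the difference was smaller than the bound. Rtp4 had a log2 difference of -3.15 (SE 0.60), with 2 of 4 Irf2_AhcKO arrays well above background, and Oas1a one of -1.59 (SE 0.33), and both were singled out after their values were seen. With normexp the difference of Rtp4 was much smaller in size. The list as a whole had a median of -0.03 and did not shift one way (camera adjusted p = 0.946), while fry's test for change in either direction gave adjusted p = 0.000591. Of 21 interferon signalling components, 3 rose over the list alone, among them Stat3 by 0.49 (SE 0.09) and Irf8 by 0.60 (SE 0.13), and the list's camera adjusted p was 0.203. Only 2 of the 10 interferon ligands were measured, Ifna1 and Ifnl3, at log2 differences of 0.01 and -0.01 (camera adjusted p = 0.963).

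**Figure D2:**
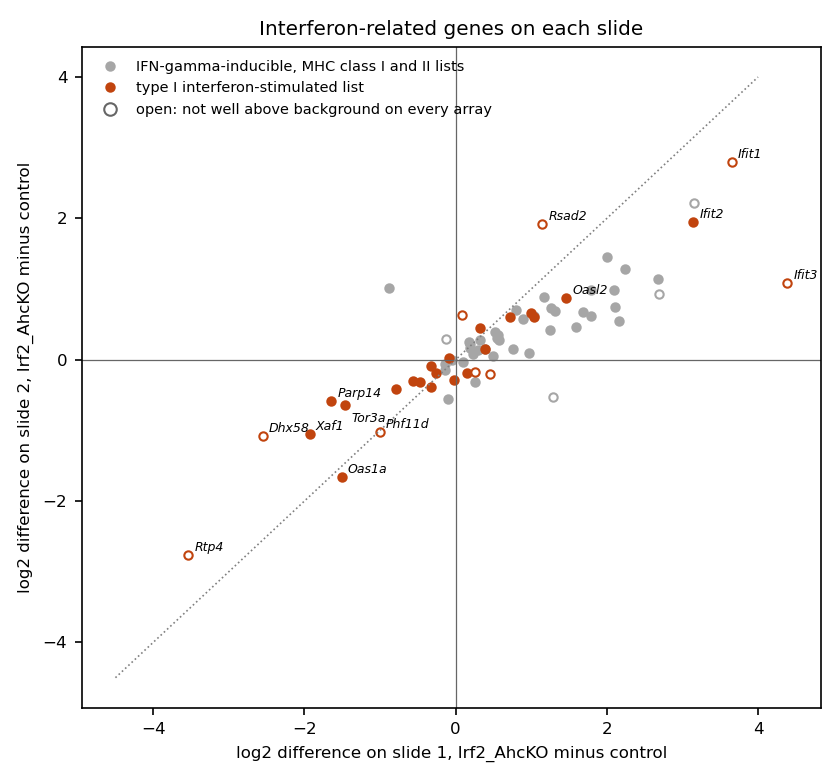
Log2 difference between Irf2_AhcKO and control arrays on slide 1 (x axis) and slide 2 (y axis), 2 against 2 arrays on each, for members of the type I interferon-stimulated list and, in grey, of the interferon gamma-inducible and MHC lists. Open points were not well above background on every array, so their place is no exact difference. Ifit2 lies at 3.14 and 1.95, and Oas1a at -1.51 and -1.67, and the dotted line marks equal differences.

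Lists tied to the absorptive lineage and to fat oxidation were lower with camera's preset correlation, while few of their members passed. Fry in 1 direction called neither, with adjusted p of 0.1125 for enterocyte markers and 0.0874 for fatty acid oxidation. Of 12 genes of fatty acid oxidation and PPAR targets, 4 fell over the list alone, among them Acadvl by 0.40 on the log2 scale (SE 0.09), the receptor Ppara by 0.40 (SE 0.11) and Acaa2 by 0.33 (SE 0.11). The list's median was -0.23, at -0.27 on slide 1 and -0.22 on slide 2 (camera adjusted p = 0.000187, and adjusted p = 0.442 with an estimated correlation). Of 22 enterocyte markers, 15 had a negative and 7 a positive difference. Fabp2 fell by 0.50 (SE 0.08) and Rbp2 by 0.88 (SE 0.18) over the list alone, while Alpi at -0.79 and Fabp1 at -0.59 did not pass. That list's median was -0.25, at -0.34 on slide 1 and -0.23 on slide 2 (camera adjusted p = 0.00787, and adjusted p = 0.442 with an estimated correlation). It was -0.14 with normexp, -0.16 without Irf2_AhcKO replicate 1 and -0.17 without control replicate 2. The marker Sis stood at 10.42 on control replicate 4 and between -1.74 and -0.79 on the other control arrays.

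Markers of the stem cells and of the secretory lineages showed few differences. The cells were sorted for high Lgr5 reporter signal, so similar stem cell marker levels in both groups are in part set by the gate. Lgr5 had a log2 difference of -0.29 (SE 0.16, limma adjusted p = 0.502), and of 27 stem cell markers only Gkn3 passed over the list alone, where it fell by 0.64 (SE 0.12), with Scn2b at -0.39, Slc14a1 at -0.55 and Ascl2 at -0.46 not passing (camera adjusted p = 0.236). Of 8 Notch pathway genes, the ligand Jag1 fell by 0.58 (SE 0.11) and Nrarp by 0.63 (SE 0.13), while Hes5 rose by 0.30 (SE 0.07) over the list alone, with Notch3 at 0.18 (camera adjusted p = 0.413). No member passed in the lists of secretory progenitor regulators (Creb3l4 -0.47, Neurog3 -0.36), Paneth cells (Mmp7 0.52, Mptx1 -0.67), goblet cells (Klk1 -0.99, Muc2 -0.30) or enteroendocrine cells (Chga 0.72, Tac1 0.54). Their camera adjusted p values were 0.263, 0.751, 0.0596 and 0.567. The Paneth median of -0.08 hides opposite values on the slides, -0.44 on slide 1 and 0.24 on slide 2, each called in a fit of that slide alone (adjusted p = 0.00669 and 0.0123) and in none of the other 21 alternatives, up to an adjusted p of 0.969. Over 23 alternatives the goblet list passed in 8, the replicate block among them (adjusted p = 0.0406), with adjusted p from 3.98e-05 to 0.738, the highest with an estimated correlation. The 11 tuft cell markers had a median of 0.28, at 0.43 on slide 1 and 0.61 on slide 2 (camera adjusted p = 0.0499, and adjusted p = 0.738 with an estimated correlation), with Trpm5 at 0.75, Dclk1 at 0.68, Siglecf at 0.98 and Avil at 0.76, none of which passed over the list alone. The shift rests on few arrays. The list mean was -0.70 on Irf2_AhcKO replicate 2 and -0.29 on replicate 3, against -1.40 to -1.07 in controls, -1.11 on replicate 4 and -1.51 on replicate 1. The tuft median was 0.01 without Irf2_AhcKO replicate 2, 0.19 without replicate 3 and 0.33 without control replicate 4, and the list did not pass in these 3 fits. It was 0.50 without Irf2_AhcKO replicate 1, 0.43 without replicate 4 and 0.10 with normexp.

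In the inflammatory cell death list, Tnfsf10 (the death ligand TRAIL) rose by 0.88 (SE 0.15) and Casp4 by 0.66 (SE 0.16) over the list alone, Gsdmd fell, and Casp1 stood at 0.31 (camera adjusted p = 0.751). Of the p53 targets, Trp53inp1 rose by 0.76 (SE 0.21) and Ccng1 fell by 0.62 (SE 0.15) over the list alone, with Sesn2 at -0.31 and Phlda3 at -0.94 (camera adjusted p = 0.275). No member passed among Wnt targets (Sp5 0.37, camera adjusted p = 0.413), reserve and regenerative markers (Ly6a 0.51, Areg 0.44, 0.413), inducible antimicrobial genes (Reg1 -1.02, Reg3g 1.16, 0.693), cell cycle genes (Cenpf -0.59, Aurkb 0.24, 0.149), unfolded protein response genes (Ddit3 -0.48, Edem1 0.15, 0.413) or aryl hydrocarbon receptor targets (Ugt1a6a -0.70, Tiparp -0.14, 0.413). Cenpf was well above background on 3 of 4 control and 1 of 4 Irf2_AhcKO arrays, and Ugt1a6a on 2 of 4 Irf2_AhcKO arrays.

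Markers of other cells were measured for carry-over. Cd79b, a B cell receptor component, rose by a log2 difference of 1.33 (SE 0.28) over its list of 5 alone, with 2 of 4 control arrays well above background, while Mzb1 (0.03) and Pou2af1 (-0.04) did not pass (camera adjusted p = 0.413). The T cell list (Nkg7 0.40, Lck 0.36), the myeloid list (Fcer1g 0.53, Cd14 0.36), the mesenchymal list (Col3a1 -0.95, Vim -0.25), the endothelial list (Egfl7 0.52, Pecam1 -0.35) and the red blood cell list (Alas2 0.32, Slc4a1 0.08) had no passing member, with camera adjusted p of 0.203, 0.634, 0.413, 0.963 and 0.413. Col3a1 was well above background on 2 of 4 arrays in each group, and Vim and Pecam1 on 2 of 4 Irf2_AhcKO arrays. The immediate early genes of dissociation had none either (Hspa1a -0.72, Jun 0.19, camera adjusted p = 0.567). Of 8 pan-epithelial genes, Krt19 fell by 0.43 (SE 0.10) over the list alone, with Epcam at -0.16, Krt8 at -0.15 and Cdh1 at -0.08 (camera adjusted p = 0.236).

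Of the 31 lists, 6 passed with camera's preset correlation, 7 with the replicate block and none with an estimated correlation. The smallest unadjusted p there was 0.0261, for fatty acid oxidation, and fry called none in 1 direction and 9 in either direction. Other splits of the 8 arrays often called as many lists: 14 of the 34 splits, the real one among them, gave 6 or more. No feature passed the test of whether the genotype difference differed between the slides (1091 had an unadjusted limma p below 0.05).

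**Figure D3:**
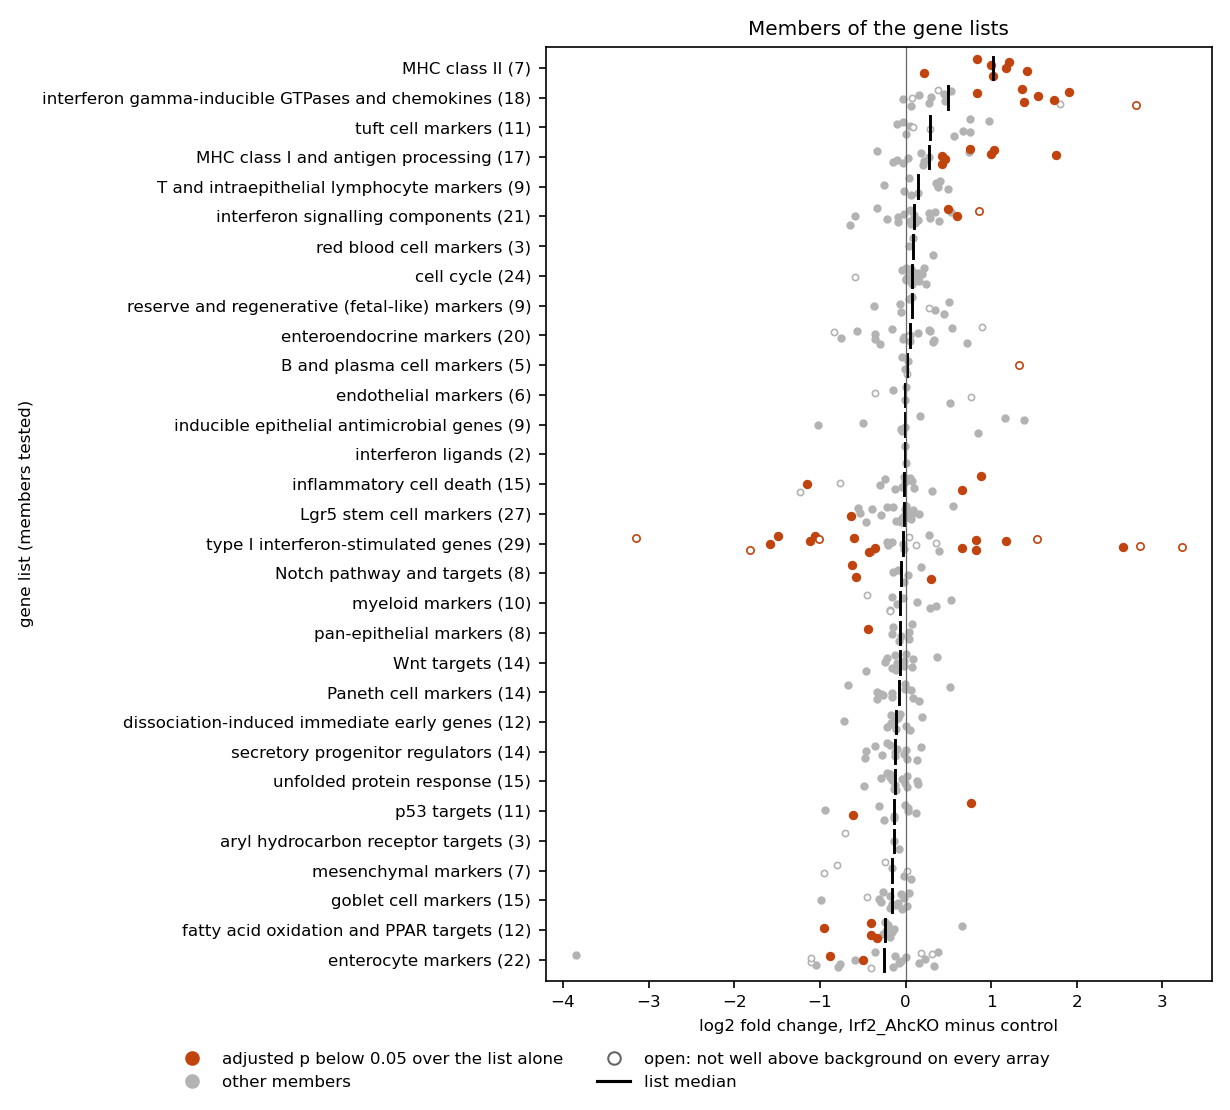
Log2 fold change of each measured member (x axis) of the 31 gene lists (y axis, with the number of members tested), from 4 control and 4 Irf2_AhcKO arrays. Points in colour have an adjusted p below 0.05 over the list alone, open points were not well above background on every array, and bars are list medians, from 1.03 for MHC class II to -0.25 for enterocyte markers.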

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

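The tests of leukocyte carry-over, of the Irf2 probe's place, of further probes and of probes near background were chosen after the results were seen, and the tests of splits and of array placement before. Of the 35 splits of the 8 arrays into 4 and 4, 34 could be fitted with the slide as a term. For the count of genes past the threshold, 1 of the 34 splits (the real one) gave as many as the real 25, and the highest of the others gave 1. The replicate numbers pair the arrays and the slide is in the model, so the comparison that counts is with the 8 splits that part all 4 same-numbered pairs or the 18 balanced over the slides. The share under 5% expected before the data were examined took all splits as alike, which this design does not allow. The highest other count was 0 in both sets, and both are too few for a share under 0.05. With the replicate block 0 genes passed. For the count of gene lists, 14 of the 34 splits, the real one among them, gave at least the real 6, and the highest of the others gave 14, so chance is not excluded. That highest split set controls 1, 2 and 3 and Irf2_AhcKO replicate 3 against the rest. On slide 1 it is the labelled contrast itself, and on slide 2 it sets replicates 3 against replicates 4, which had Xist signal. Its count is therefore no pure measure of chance. Among the 8 splits that part all pairs, the highest other count was 8 lists, and 3 of the 8 gave at least 6. List by list, the interferon gamma-inducible and MHC class I lists each had a camera p as small in 1 of 34 splits (the real one), the enterocyte and fatty acid oxidation lists in 2, MHC class II in 3 and tuft cell markers in 15.

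The type I interferon-stimulated genes passed in opposite directions, 8 higher and 10 lower over the list alone. Single probes that cross-hybridise are argued against by the further probes: in the 5 passing genes with a further kept probe, all 5 further probes had the sign of the brightest one. Probes near background are argued against too, since among members well above background on all 8 arrays 5 passed higher and 7 lower. The other 13 passing genes rest on 1 probe each, and for those, Ifit1 with its near-copy Ifit1bl1 included, cross-hybridisation stays open. A biological hypothesis is that the genes depend on IRF2 in different ways, which these data did not test.

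The MHC class II genes were higher in the arrays labelled Irf2_AhcKO, by a mean log2 shift of 0.98 (95% interval 0.13 to 1.84) over 7 genes. Leukocytes carried into the sort may have brought such transcripts. The gate on the Lgr5 reporter selects against them, but 20 leukocyte markers, Ptprc and Cd3e among them, were well above background on all 8 arrays. The 20 leukocyte markers above background shifted by 0.12 (0.02 to 0.22), and the difference between the 2 shifts had a lower limit of 0.0132. Cd74 and its relatives are made by B and myeloid cells, Cd79b was higher and Cd79a, at -0.00295, was not. The myeloid markers Itgam (7.26) and Csf1r (4.52) had a high level in controls that would hide a small share. Other myeloid markers had a low level, among them C1qa (-2.99) and Fcer1g (-2.89), so that limit does not hold for them. Carry-over and induction in the stem cells cannot be told apart here, because the lower limit for the leukocyte markers also lay above 0. That rests on their mean alone: 8 of the 20 had a negative difference, and no T cell or myeloid list member passed.

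Irf2 was not lower in the arrays labelled Irf2_AhcKO. A single mislabelled array is argued against: on 100 higher and 100 lower genes chosen on the other slide, 8 of 8 arrays fell on the side of their own label, with scores from -0.94 to -0.40 in controls and from 0.49 to 0.75 in Irf2_AhcKO. That the only Irf2 probe, with a log2 difference of 0.275, lies outside the deleted part is a possible explanation that cannot be told apart from incomplete deletion, since the probe's position is not given in the sources used here. It also stays open whether control replicates 3 and 4, whose scanner data names mention Ah-Cre, carried the recombinase, although Irf2 was not lower on slide 1 either, without those controls (0.34). On genes chosen on slide 1, these controls scored -0.71 and -0.53, and Irf2_AhcKO replicates 3 and 4 scored 0.49 and 0.75. That argues against these controls fully sharing the profile of the Irf2_AhcKO arrays, and does not show which transgenes they carried. Scores were taken relative to the slide's own mean, so sharing in part cannot be seen. List medians on slide 2 were smaller than on slide 1 for interferon gamma (0.47 against 1.00) and MHC class II (0.62 against 1.59). The tuft median was larger there (0.61 against 0.43). Whether these controls had a part in that was not tested.

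Of 296 groups of 4 arrays examined (named genes, list means and array statistics), 18 held 1 array far from the other 3, where chance gives about 1 in 20. Values are log2 signals relative to the array's 75th percentile. Sis stood at 10.42 on control replicate 4, with the other controls between -1.74 and -0.79. On that array H2-Eb1 was at -0.52 and Jag1 at -0.60. Control replicate 1 had Ifit2 at -2.89 and control replicate 2 had Klk1 at 1.08. Control replicate 3 had the mean of interferon signalling components at 0.16 and that of interferon ligands at -1.29. Irf2_AhcKO replicate 4 had Cadps2 at -2.46, Akr1c14 at -2.92, Cdh1 at 0.91, Reg3g at 6.16 and the mean of inducible antimicrobial genes at 1.77. Irf2_AhcKO replicate 2 had Tapbp at 3.04 and Casp1 at 3.73. Irf2_AhcKO replicate 1 had Ifna1 at -1.98, Cd79b at -2.73 and a 75th percentile of processed signal of 212.5, and Irf2_AhcKO replicate 3 had a mean of myeloid markers of -0.0546.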

How the results depend on the processing

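Testing only features with a symbol and leaving out both arrays with Xist signal were chosen after seeing the data, and the other alternatives before. Against 25 calls (14 higher, 11 lower), normexp gave 133 (71 and 62, 24 of them shared with the 25), trended and robust eBayes 133 (72 and 61, 25 shared), the filter on all 8 arrays 46 (28 and 18), the random slide block 44 (29 and 15), no filter 7 (3 and 4) and no slide term 19 (14 and 5). The mean of a gene's probes gave 21 (9 and 12). The replicate block gave 0 genes, 0 higher and 0 lower (limma, 3293 at unadjusted p below 0.05), and slide 1 and slide 2 alone each 0, 0 and 0 (2539 and 1337). Without both Xist arrays 1 gene passed, 1 higher and 0 lower. The causes were not tested, except that the slide-alone and left-out fits have fewer arrays. Leaving out 1 array gave 0 to 25 calls, 0 to 15 higher and 0 to 10 lower: 11 without control replicate 1, 0 without control replicate 2, 6 without control replicate 3, 25 without control replicate 4, 0 without Irf2_AhcKO replicate 1, 0 without replicate 2, 1 without replicate 3 and 3 without replicate 4.

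The number of called lists, 6, ranged from 5 to 11 when 1 array was left out (11 without control replicate 4) and was 0 with an estimated correlation. The replicate block gave 7. The interferon gamma, MHC class I, MHC class II, enterocyte and fatty acid oxidation lists each passed in 22 of 23 alternatives, all but the estimated correlation, and the tuft list in 14. Tested with fry in 1 direction, which was run beside camera, none passed. Irf2 lay between 0.17 and 0.35 and never passed. The interaction count was 0 in each of its 3 settings (1091, 1693 and 1157 at unadjusted limma p below 0.05). Over the alternatives, the 6 called lists kept their call in 124 cases and lost it in 14. The 23 called genes with a symbol kept it in 220 and lost it in 282, each of them in some alternative. Cadps2 kept its call most often, in 15 of 22 alternatives, and Lgi3 least often, in 4 of 21. Tapbp kept its call in 5 of 22 and lost it whichever array was left out. Uncalled results gained a call in 23 cases for lists and 39 for named genes. With normexp 10 of these 23 gene values and 3 of the 6 list medians moved by more than 1.5 times (interferon gamma 0.24, tuft 0.10, enterocyte -0.14). Signal over background limits Ifit1, C4bp, Cd274, Dhx58 and Gsta4, which have only bounds, and Rtp4. With normexp Cd274 stood at 0.60, Dhx58 at -0.29, Gsta4 at -0.13 and Rtp4 at -0.95.

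The reversed results reported here were all uncalled in the reported setting, and 1 was called in the alternative. Values are log2 differences, for lists the median, whose camera direction turned even where the median kept its sign. Type I interferon-stimulated genes stood at -0.0257 with normexp, -0.0509 with mean probes, -0.0321 with trended eBayes and -0.0321 with symbols only. Interferon ligands stood at 0.110 on slide 1, 0.0575 with mean probes, 0.0288 in the series table, -0.000819 with symbols only and 0.0895 without both Xist arrays. Aryl hydrocarbon receptor targets were at 0.0741 and endothelial markers at -0.00038 without the filter, and inflammatory cell death at -0.00144 with the filter on all 8 arrays. On slide 2 the Paneth list was at 0.242 (called, adjusted p = 0.0123, against -0.437 and 0.00669 on slide 1, also called, and up to 0.969 in the other alternatives), the unfolded protein response at 0.0891, mesenchymal markers at 0.140 and endothelial markers at 0.0205. Ifna1 was at -0.0520 with normexp, -0.0143 with quantile normalization and -0.159 on slide 2. Ifnl3 was at 0.0460 on slide 1, 0.107 with mean probes, 0.0200 in the series table and 0.00493 without both Xist arrays. Pou2af1 was at 0.0167 on slide 1 and 0.0444 without both Xist arrays, and Slc4a1 at -0.0591 without them. On slide 2 Mptx1 was at 0.270, Mzb1 at -0.0016 and Vim at 0.236. With 1 array left out, the ranges were -0.26 to 0.0150 for the Paneth list, -0.0735 to 0.0665 for endothelial markers, -0.331 to 0.171 for immediate early genes, -0.0737 to 0.0854 for interferon ligands, -0.0846 to -0.0219 for type I targets, -0.229 to 0.00607 for the unfolded protein response, -0.0361 to 0.128 for enteroendocrine markers and -0.0494 to 0.0484 for antimicrobial genes. For Ifna1 it was -0.134 to 0.182, for Pou2af1 -0.184 to 0.0976, for Ifnl3 -0.0345 to 0.0144 and for Slc4a1 -0.00751 to 0.149. The cause was not tested.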

Other observations

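All families, genes and tests in this part were chosen after the values were seen, by symbol prefix, so their p values are descriptive. Among 11 such families, the glutathione transferases, which conjugate glutathione to electrophiles, were lower in the arrays labelled Irf2_AhcKO, with 19 of 23 members negative and a median log2 difference of -0.22, at -0.22 on slide 1 and -0.23 on slide 2 (camera adjusted p = 7.93e-07, and adjusted p = 0.0375 with an estimated correlation). Gstt1 had a log2 difference of -1.19 (SE 0.14, limma adjusted p = 0.0502), just short of the threshold over all genes, and Gsta4 was at least 1.51-fold lower (adjusted p = 0.0768), with no Irf2_AhcKO array well above background. The bound for Gsta4 holds for the processed signal only, and with normexp its difference was smaller than the bound. Carboxylesterases had a median of -0.54, UDP-glucuronosyltransferases -0.39, aldo-keto reductases -0.31, aldehyde dehydrogenases -0.12 and cytochrome P450 enzymes -0.10, with camera adjusted p of 0.000748, 0.000235, 0.00196, 0.00462 and 0.00334 and, with an estimated correlation, adjusted p of 0.0545, 0.0545, 0.198, 0.0545 and 0.0986. Of the 9 carboxylesterases, 7 were negative and 2 positive. The positive Ces1g had a log2 difference of 1.08 (SE 0.19, limma adjusted p = 0.001855 over the family alone). All 6 medians stayed negative with normexp, quantile normalization and the series table, but with normexp they were nearer 0: glutathione transferases -0.16, carboxylesterases -0.53, UDP-glucuronosyltransferases -0.18, aldo-keto reductases -0.14, aldehyde dehydrogenases -0.10 and cytochrome P450 enzymes -0.05. Enterocyte markers, given in the report, had a similar median of -0.25 (camera adjusted p = 0.00787, and adjusted p = 0.442 with an estimated correlation), with 2 of 22 passing over the list alone. A fall of the families apart from that of the enterocyte markers was not tested.

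Apolipoprotein L genes, known as interferon-inducible in part, had a median of 0.69 (0.40 with normexp), with 6 of 8 positive (camera adjusted p = 0.000748, and adjusted p = 0.0545 with an estimated correlation). Apol7a had a log2 difference of 2.90 (SE 0.37, limma adjusted p = 0.0658) and Apol7c one of 1.63 (SE 0.24, adjusted p = 0.099), each well above background on 2 of 4 control arrays, and members of this family are similar in sequence. Ribosomal protein genes had a median of -0.11, with 76 of 78 negative (camera adjusted p = 7.81e-10, and adjusted p = 0.324 with an estimated correlation), and 4 of 34 splits gave as small a p. The median was -0.07 with quantile normalization, and no member passed over the family alone (lowest limma adjusted p = 0.281). Trim genes (-0.02) and core histone H2B genes (0.02) had camera adjusted p of 0.628 and 0.127, and both medians change sign with some scaling.

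The hypothesis that glutathione transferase genes fall together may hold beyond 1 slide: on slide 2 alone limma's camera gave a p of 2.25e-06 (adjusted over the 11 families, 2.48e-05) in the direction seen on slide 1. Slide 2 is not independent evidence, since the family was picked with all 8 arrays in view. The like hypothesis for proteasome subunits had a camera p of 0.0384 on slide 2 (adjusted, 0.0469), but over all arrays the family missed the threshold (camera adjusted p = 0.127), its median of 0.01 turned to -0.01 with normexp, and 10 of 34 splits gave as small a p, so it stays open.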
